A study of Homo sapiens with 12 samples.

How the data were processed

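RNA sequencing measured transcript levels in 12 cultures of RD cells, a human rhabdomyosarcoma line, 96 hours after reverse transfection with siRNA. The samples form 4 groups of 3, which the labels call biological replicates. In experiment 1 an siRNA against LSD1 (the protein made from the gene KDM1A), named siLSD1-2, was set against control siRNA. In experiment 2 another siRNA against LSD1, named siLSD1-3, was set against its own control siRNA libraries. Each siRNA was used in 1 experiment, so siRNA and experiment are confounded.

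The deposited values are normalised read counts, a signal per RefSeq transcript on hg19. HOMER's analyzeRepeats.pl counted reads in exons on both strands and getDiffExpression.pl made the comparison, per the file headers. TopHat, HOMER and edgeR, without versions, are named per the submitters' processing notes. The authors' tables also hold a log2 fold change and a p-value with its adjusted p-value per transcript, which were used only for a comparison with the refit. Checked on the values, each deposited column equals whole reads times 1 factor per library, so that the 6 libraries of a table share a total of about 51.1 M in experiment 1 and 74.1 M in experiment 2. Dividing by that factor gave whole reads for 100% of positive values within 0.1 of a read. Recovered reads over all transcript rows were 75.5 to 116.6 M per library in experiment 1 and 58.8 to 95.8 M in experiment 2, where a read counts once for each transcript it overlaps. Even read counts were in slight excess (51.0 to 54.0% of values from 1 to 100 reads), and the deposited files do not say why.

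Each of the 2 tables had 38763 transcript rows. The 1138 rows with no gene symbol held 0.300 to 0.330% of reads and were left out of the tests and of the totals used for scaling. Where a symbol had several rows (7316 symbols), the row with the most reads over all samples stood for the gene. That left 24331 rows and 31.3 to 62.2 M reads per library, both counted with the 1138 rows without a symbol still included. For 459 rows the tables give different symbols, and 548 rows list several genomic copies. The tables hold 0 rows on the mitochondrial chromosome. Coordinates are those of the files, on hg19. The header of the experiment 2 table also names libraries of an siRNA called siLSD1_1, which were not analysed here. GRCh38 gene tables were used only for names and GC content, which was available for 98.9% or more of the tested genes of each experiment.

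The planned test was edgeR's quasi-likelihood test, for tables of raw counts. Because the deposited values are normalised, the test used is limma (3.58.1, with a trend) on log2(CPM + 0.1), from CPM (counts scaled to a common library total, computed here from the deposited values with TMM scaling) after edgeR's (4.0.16) filterByExpr with a minimum count of 10. That minimum of 10 is in deposited units, not reads. A read equals 0.438 to 0.677 units in experiment 1 and 0.774 to 1.26 in experiment 2, so the filter differs between experiments. Fold changes are on the log2(CPM + 0.1) scale, which understates the change of low genes. Each experiment was fitted alone (3 control and 3 knockdown libraries), and the difference between siRNAs in 1 fit of 4 group means. Adjusted p-values are Benjamini-Hochberg, with calls below 0.05. Values after ± are SD over 3 libraries, and SE is limma's standard error. R was 4.3.3 and Python 3.11.15.

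Lists of genes were tested with camera (preset correlation 0.01, adjusted over 30 lists). Camera with an estimated correlation and fry, which does not compare a list with other genes, stood beside it. The 31 lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. The lists covered adhesion and matrix (integrins, focal adhesion and integrin adaptors, cadherins and catenins, immunoglobulin-superfamily adhesion molecules, collagens, basement membrane, matricellular and matrix glycoproteins, matrix proteases and inhibitors, ephrins with semaphorins and plexins), cell identity (epithelial, mesenchymal transition, myogenic regulators, muscle differentiation, neuronal genes repressed by REST, blood cell and endothelial markers), signalling and stress (interferon-stimulated, inflammatory cytokines, YAP and TGF-beta, Notch with WNT and Hedgehog, p53 targets, heat shock, unfolded protein response, immediate early, glycolysis and hypoxia, cholesterol synthesis), proliferation, LSD1 partners, the RNA interference machinery, ribosomal proteins and mitochondrially encoded genes. The last list has 0 measured members.

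The rule for named genes takes KDM1A. Per siRNA it takes the 8 genes with the largest change each way among protein-coding genes past the threshold whose 3 knockdown and 3 control values do not overlap and whose higher mean is at least 1 CPM. It takes by the same limits the 10 each way with the largest smaller change for both siRNAs, the 5 largest differences each way, and up to 4 members of each described list with the smallest p. From these, the genes in the text were chosen after their values were seen, with preference for siLSD1-3 genes whose call survived each left-out library. Some genes are not reported here.

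The tests were checked on 10 simulated sets per experiment, drawn from the real means and library sizes with 200 changed genes. The changed genes and the lists came only from genes above a minimum mean read count, so recovery of genes below it was not tested. These sets held far fewer changed genes than were called in the data, so their share of false calls may not carry over. For siLSD1-2 (15414 genes on average) 70.4, 93.1 and 99.5% of genes changed by 1.5, 2 and 4 fold were recovered, and 7.37% of calls were false. For siLSD1-3 (15122 genes) these were 61.8, 94.8 and 99.8%, and 7.32%. Camera called 0 of 290 unchanged lists for either siRNA at the preset correlation, and a planted list of 40 genes changed by 1.5 fold in 10 of 10 sets for either. With an estimated correlation the planted list was also called in 10 of 10 sets. Simulated genes were drawn independently and without letter pairs, so these sets do not test camera on correlated genes. Regrouping the real libraries with knockdown and control mixed gave up to 20 lists for siLSD1-2 and 9 for siLSD1-3. These regroupings keep more knockdown than control libraries on the knockdown side. Part of the knockdown effect therefore remains, and the counts do not give the number of lists called without an effect.

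The deposited columns carry letters a, b and c, not replicate numbers. Deviations from group means of same-letter libraries correlated at 0.22, 0.68 and 0.49 in experiment 1 and 0.58, 0.76 and 0.57 in experiment 2 (a, b and c, across genes). All lie above 0.1, so a fit with the letter as a block is given beside results it changes. Control library c and siLSD1-3 library a of experiment 2, with different letters, correlated at 0.33. That is above the a pair of experiment 1, so the limit of 0.1 does not single out same-letter pairs. The pairing rests on these correlations, not on the labels, and was decided before blocked calls were compared.

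That first set of alternatives held other scalings, filters and tools (DESeq2 1.42.0, limma voom), every row tested, all 12 samples in 1 fit, leaving out each library, fry and the estimated correlation. The choice of limma with a pseudocount of 0.1 was settled after a first exploratory edgeR fit. Pseudocounts of 0.5 and 1, edgeR on recovered reads, the letter block, removal of the GC trend per library, and a fit without the c pair of experiment 1 and the b pair of experiment 2 were added after seeing the data. Counting on both strands cannot separate overlapping or antisense genes. Among the genes named this concerns GPR17 with LIMS2, RIMS4 with KCNK15, MMP1 with WTAPP1, PLAU with C10orf55, SLC16A6 with ARSG, PTCH1 with LOC100507346, ITGB2 with ITGB2-AS1, MSC with LOC100132891, THY1 with USP2-AS1 and TAS2R19 with PRH1-PRR4, whose values are uncertain to that extent. TNXB is listed with 7 copies and is also uncertain.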

Results

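RNA sequencing was used to ask how lowering LSD1, a histone demethylase encoded by KDM1A, changes gene expression in RD rhabdomyosarcoma cells, with adhesion named in the series title. Total RNA came from 12 cultures harvested 96 hours after transfection. Experiment 1 held 3 control siRNA and 3 siLSD1-2 libraries, and experiment 2 held 3 control siRNA and 3 siLSD1-3 libraries. After 1 transcript row was kept per gene, the libraries held 40.3 to 62.2 M reads in experiment 1 and 31.3 to 51.3 M in experiment 2, rows without a symbol included. Values are CPM (read counts scaled to a common library total) computed from the authors' normalised read counts.

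KDM1A mRNA (NM_001009999, hg19 chromosome 1, 23345941 to 23410184) was lower in each of the 6 knockdown libraries than in any control library. In experiment 1 it fell from 317 ± 13.9 CPM with control siRNA to 27.2 ± 18.6 CPM with siLSD1-2 (SD, n = 3 each), or 8.58% of control. The 3 siLSD1-2 libraries held 18.1, 14.9 and 48.6 CPM. In experiment 2 it fell from 351 ± 10.6 to 24.8 ± 4.17 CPM with siLSD1-3, or 7.08% of control, with 22.7, 29.6 and 22.1 CPM in the 3 libraries. The log2 fold changes for KDM1A were -3.74 (SE 0.36, limma adjusted p = 0.000116) and -3.83 (SE 0.11, adjusted p = 2.15e-06). Their difference was 0.07 (adjusted p = 0.921). Without library c of siLSD1-2, the KDM1A difference was -0.46 with an adjusted p of 0.048.

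**Figure D1:**
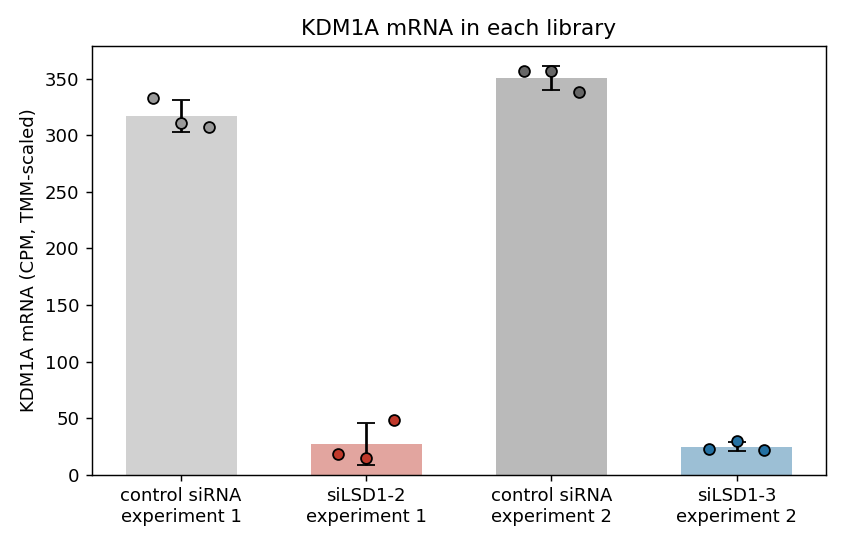
KDM1A mRNA in CPM in each of the 12 libraries (points), with group means (bars) and SD (error bars). The knockdown libraries lie between 14.9 and 48.6 CPM, and the control means are 317 and 351 CPM.

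With siLSD1-2, 13 of 30 lists rose and 5 fell (camera, preset correlation), among them interferon-stimulated genes (42 of 47 rose) and proliferation genes (46 of 50 fell). With an estimated correlation 0 lists passed (adjusted p = 0.304 for interferon-stimulated and adjusted p = 0.365 for proliferation genes; 3 of 30 lists at an unadjusted p below 0.05), and fry called 23. The tight junction gene CLDN4 (NM_001305, chromosome 7, 73245193 to 73247015) rose from 0.688 ± 0.0678 to 30 ± 7.44 CPM (log2 fold change 5.23, SE 0.19, adjusted p = 3.55e-06). The neutrophil-attracting chemokine gene CXCL8 rose from 0.951 ± 0.105 to 23.7 ± 4.43 CPM (4.49, SE 0.16, adjusted p = 3.55e-06), and the cation channel gene TRPV2 from 0.398 ± 0.024 to 11.6 ± 1.54 CPM (4.55, SE 0.16, adjusted p = 3.55e-06). Log2 fold changes were 4.87 for PTPRN, 4.68 for the guidance receptor gene ROBO4 and 4.48 for RRAD. Among the genes that fell most, the collagen gene COL1A2 went from 72.6 ± 15.6 to 19.4 ± 10.4 CPM (-2.03, SE 0.36, adjusted p = 0.00209), ARHGAP15 fell by 2.01 and RGR by 1.89 on the log2 scale.

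Over 14987 genes tested with siLSD1-2, 3670 rose and 3331 fell (limma, adjusted p below 0.05), and of these 1051 rose and 201 fell by 2 fold or more. The 3 knockdown and 3 control values did not overlap for 57.0% of genes, where chance gives 10%. The first principal component held 83.6% of the variance, and siLSD1-2 library c, which kept the most KDM1A mRNA, lay nearer to the controls (16.4) than libraries a and b (31.9 and 30.8).

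Integrin genes, which encode the receptors that attach cells to matrix, rose with siLSD1-2 in 13 of 20 cases and fell in 3 (13 and 4 adjusted over the list alone), with a median log2 fold change of 0.88. The list passed with an adjusted p of 0.0014 (camera, preset correlation) and an adjusted p of 0.304 with an estimated correlation. ITGA3 (NM_002204, chromosome 17, 48133340 to 48167849) rose from 42 ± 2.49 to 240 ± 49.8 CPM (log2 fold change 2.49, SE 0.14, adjusted p = 1.65e-05). ITGB3 rose from 61.6 ± 4.33 to 226 ± 49.6 CPM (1.85) and ITGA11 from 5.03 ± 1.62 to 40.8 ± 11.1 CPM (3.00). Matrix proteases and their inhibitors rose in 34 of 42 cases and fell in 3 (35 and 4 adjusted over the list alone; median 0.84), with a camera adjusted p of 1.78e-09 and an adjusted p of 0.304 with an estimated correlation. The urokinase gene PLAU rose from 125 ± 13.1 to 413 ± 54.1 CPM (1.72), its receptor gene PLAUR from 44.2 ± 1.22 to 213 ± 44.3 CPM (2.24), and the collagenase gene MMP1 from 0.503 ± 0.211 to 8.77 ± 0.787 CPM (3.94). Reads of PLAU and MMP1 cannot be told apart from those of overlapping genes.

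Immunoglobulin-superfamily adhesion molecules rose in 20 of 32 cases and fell in 2 (22 and 3 adjusted over the list alone; median 0.55), with a camera adjusted p of 0.000451 and an adjusted p of 0.304 with an estimated correlation. NTM (2.28), ICAM1 (1.83) and L1CAM (1.47) were among those that rose. Matricellular and matrix glycoproteins rose in 20 of 36 cases and fell in 7 (22 and 8 adjusted over the list alone; median 0.62), with a camera adjusted p of 0.00056 and an adjusted p of 0.304 with an estimated correlation. LUM, a matrix proteoglycan, rose from 7.39 ± 0.276 to 18.9 ± 0.757 CPM (1.35). Focal adhesion and integrin adaptor genes rose in 19 of 39 cases and fell in 6 (19 and 6 adjusted over the list alone; median 0.28), with a camera adjusted p of 0.00822 and an adjusted p of 0.365 with an estimated correlation. CAV2 (1.56) was among those that rose. YAP and TGF-beta responsive genes rose in 17 of 30 cases and fell in 1 (17 and 2 adjusted over the list alone; median 0.40), with a camera adjusted p of 0.000369 and an adjusted p of 0.304 with an estimated correlation. AXL (1.76), ANKRD1 (1.82) and CTGF (1.11) rose. Ephrins, semaphorins and plexins rose in 17 of 40 cases and fell in 3 (17 and 4 adjusted over the list alone; median 0.31; camera adjusted p = 0.00918; adjusted p = 0.36 with an estimated correlation), SEMA7A by 2.16 and SEMA3C by 1.22.

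Interferon-stimulated genes rose with siLSD1-2 in 42 of 47 cases and fell in 0 (42 and 2 adjusted over the list alone), with a median log2 fold change of 0.87. The camera adjusted p was 2.98e-14, and the adjusted p was 0.304 with an estimated correlation. IFIT2 rose from 90.1 ± 9.32 to 239 ± 28.9 CPM (1.40, SE 0.10, adjusted p = 4.11e-05), IFIT3 from 98.8 ± 3.14 to 232 ± 13.2 CPM (1.23), SAMD9L by 1.36 and IFI44L by 1.30. Of 29 fixed inflammatory cytokine genes 18 passed the filter, of which 16 rose and 0 fell (17 and 0 adjusted over the list alone, median 1.45). The camera adjusted p was 2.65e-07, and the adjusted p was 0.304 with an estimated correlation. Members too low in controls pass the filter only where they rise, so 16 of 18 overstates the share of the list that rose. LIF rose from 15 ± 3.64 to 45.9 ± 10.6 CPM (1.61).

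Markers of other cell types also moved with siLSD1-2. Of 34 fixed epithelial marker and junction genes 16 passed the filter, of which 14 rose and 0 fell (14 and 1 adjusted over the list alone, median 1.17). The camera adjusted p was 1.55e-05, and the adjusted p was 0.272 with an estimated correlation. Here too low members enter only where they rise, so 14 of 16 overstates the share of the list that rose. Apart from CLDN4, KRT7 reached 2.22 ± 0.328 CPM and EPCAM 1.46 ± 0.349 CPM. Neuronal genes repressed by REST rose in 18 of 32 cases and fell in 3 (18 and 3 adjusted over the list alone; median 0.54), with a camera adjusted p of 0.0014 and an adjusted p of 0.341 with an estimated correlation. The synaptotagmin gene SYT11 rose from 178 ± 9.17 to 404 ± 37.5 CPM (1.18). Endothelial markers rose in 4 of 8 measured cases and fell in 0 (6 and 0 adjusted over the list alone; median 0.80; camera adjusted p = 0.00918; adjusted p = 0.341 with an estimated correlation), among them the receptor gene TIE1 (3.29). The endothelial list has 15 fixed members and the REST list 45, so low members also enter these lists only where they rise. That selection affects the medians and camera values of such lists as well as the shares. Blood cell markers, of which 6 were measured, did not pass (camera adjusted p = 0.218). CD68 (2.98), LAPTM5 (2.26) and LYZ (1.51) rose and ITGB2 (-1.30) and CORO1A (-0.31) fell. The adjusted p of ITGB2 was 0.0609 without control library a and 0.0561 without siLSD1-2 library b, and that of CORO1A (0.0493) was 0.056 to 0.183 without any 1 library, 0.0593 with library totals only, and 0.055 and 0.0547 with the other filters.

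Proliferation genes fell with siLSD1-2 in 46 of 50 cases and rose in 0 (48 and 0 adjusted over the list alone), with a median log2 fold change of -0.69. The camera adjusted p was 1.64e-13, and the adjusted p was 0.365 with an estimated correlation. The mitotic kinase gene AURKB fell from 104 ± 5.78 to 52.3 ± 8.73 CPM (-1.0, SE 0.11, adjusted p = 0.000228), and the replication gene CDC45 from 48.8 ± 8.27 to 20 ± 5.73 CPM (-1.31). Myogenic regulators fell in 10 of 20 cases and rose in 4 (10 and 4 adjusted over the list alone; median -0.24), with a camera adjusted p of 0.0262 and an adjusted p of 0.305 with an estimated correlation. MSTN, which encodes myostatin (NM_005259, chromosome 2, 190920426 to 190927455), fell from 842 ± 68.3 to 268 ± 72.7 CPM (-1.68, SE 0.16, adjusted p = 0.000116), and the muscle transcription factor gene MYOD1 from 142 ± 5.76 to 73.4 ± 13.9 CPM (-0.96). Muscle differentiation and contractile genes fell in 17 of 46 cases and rose in 6 (18 and 6 adjusted over the list alone; median -0.43; camera adjusted p = 0.0344; adjusted p = 0.734 with an estimated correlation). NEB fell by 0.81 and TPM2 fell by 0.65 on the log2 scale, whereas FBXO32, a ubiquitin ligase gene of muscle atrophy, rose by 1.51. The muscle list did not pass without control library b (adjusted p = 0.195), siLSD1-2 library a (0.0831) or siLSD1-2 library c (0.0767).

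Ribosomal protein genes, fixed as a sign of RNA quality, fell with siLSD1-2 in 41 of 76 cases and rose in 0 (46 and 0 adjusted over the list alone; median -0.22; camera adjusted p = 1.22e-08; adjusted p = 0.341 with an estimated correlation). The RNA interference machinery fell in 7 of 13 cases and rose in 0 (9 and 0 adjusted over the list alone; median -0.26; camera adjusted p = 0.00918; adjusted p = 0.304 with an estimated correlation), with AGO2 at -0.56 and DROSHA at -0.59. Targets of p53 rose in 7 of 23 cases and fell in 0 (6 and 0 adjusted over the list alone; median 0.22; camera adjusted p = 0.049; adjusted p = 0.365 with an estimated correlation), with GADD45A at 0.76. The p53 call was lost without control library a (adjusted p = 0.0646) or c (0.0791) and without siLSD1-2 library a (0.0685) or b (0.0579). Lists that did not pass with siLSD1-2 were immediate early genes (camera adjusted p = 0.0674), mesenchymal transition regulators (0.0707, and 0.0424 with the letter block; unblocked adjusted p = 0.304 with an estimated correlation), glycolysis and hypoxia (0.0909), basement membrane (0.113), LSD1 partners (0.156), cadherins and catenins (0.198), cholesterol synthesis (0.299), Notch, WNT and Hedgehog responsive genes (0.516), collagens (0.539), heat shock (0.676) and the unfolded protein response (0.862).

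**Figure D2:**
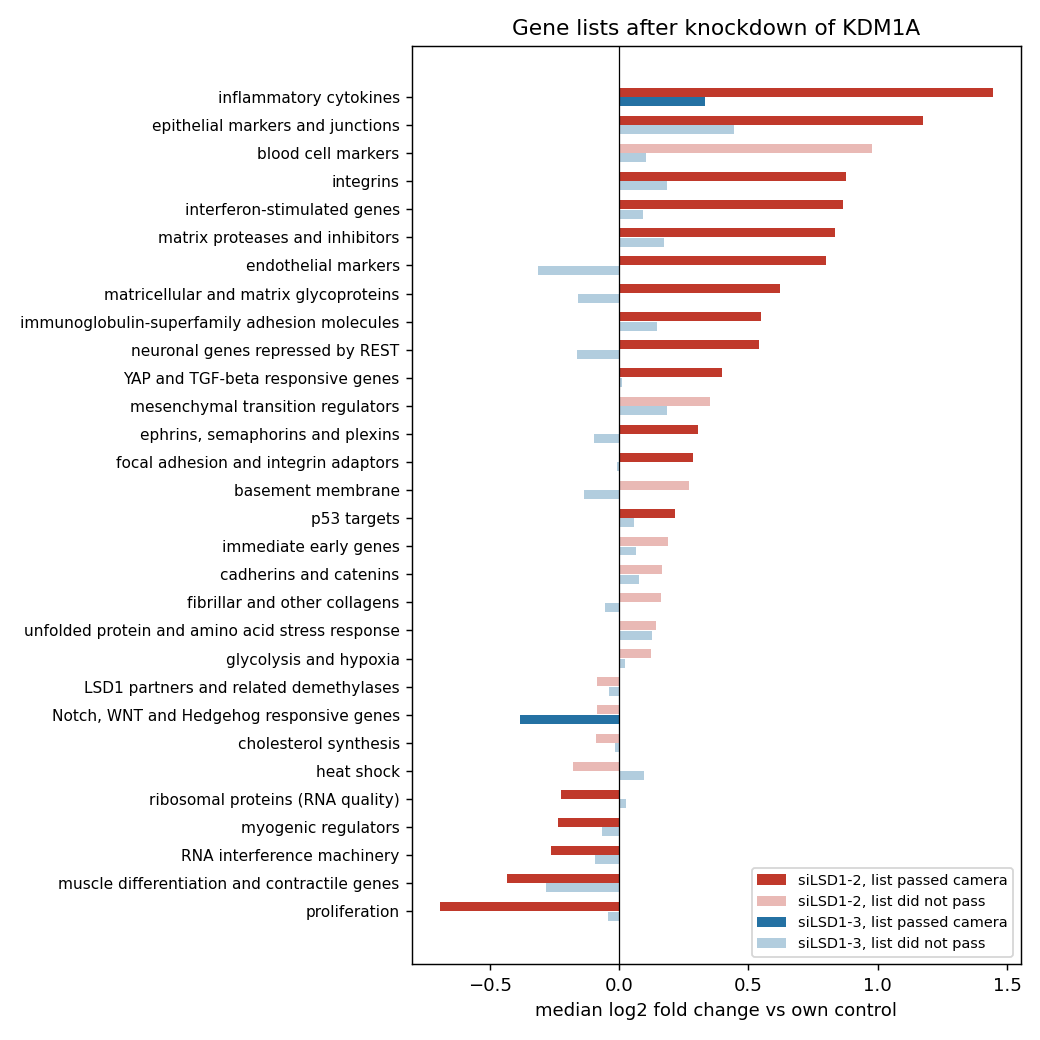
Median log2 fold change against the experiment's own control for each of the 30 tested lists with siLSD1-2 and siLSD1-3. Solid bars passed camera at the preset correlation (18 lists with siLSD1-2, 2 with siLSD1-3) and faint bars did not.

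With siLSD1-3, 2 of 30 lists passed (camera, preset correlation), with Notch, WNT and Hedgehog responsive genes lower (17 of 39 fell) and inflammatory cytokine genes higher (7 of 20 rose). With an estimated correlation 0 lists passed (adjusted p = 0.508 and adjusted p = 0.618 for these 2; 2 of 30 lists, the Notch list and integrins, at an unadjusted p below 0.05), and fry called 7. The complement receptor gene C3AR1 (NM_004054, chromosome 12, 8210919 to 8218955) rose from 1.68 ± 0.538 to 15.1 ± 3.25 CPM (log2 fold change 3.11, SE 0.24, adjusted p = 0.00115). The G protein gene GNA15 rose from 0.264 ± 0.11 to 2.49 ± 1.17 CPM (2.74) and the lectin gene SIGLEC15 from 1.87 ± 0.475 to 11.2 ± 1.9 CPM (2.54). The sulfotransferase gene CHST8 fell from 4.8 ± 1.31 to 1.1 ± 0.462 CPM (-2.07), and the ephrin gene EFNA2 from 4.04 ± 0.13 to 0.951 ± 0.291 CPM (-2.01, SE 0.22, adjusted p = 0.00221). CXCL8 went from 1.04 ± 0.54 to 13.4 ± 13.6 CPM (3.22, SE 0.62, adjusted p = 0.0152), and without control library c its adjusted p was 0.0642.

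Of 15141 genes tested with siLSD1-3, 1059 rose and 1006 fell, and 194 of them rose and 167 fell by 2 fold or more. With the column letter as a block, 2894 rose and 2885 fell. The values of the 3 knockdown and 3 control libraries did not overlap for 36.5% of genes, where chance gives 10%. The sum of both directions, 2065, became 601, 1211 or 444 without control library a, b or c, and 1160, 3566 or 645 without siLSD1-3 library a, b or c. The first principal component held 64.3% of the variance and placed siLSD1-3 library b (2.67) nearer to the controls than libraries a and c (26.7 and 15.2). Fold changes with siLSD1-3 were also related to GC content across genes (Spearman rho -0.44 over 10790 genes, which are not independent replicates). The median log2 fold change went from 0.14 in the lowest of 10 equal groups of genes by GC content to -0.22 in the highest. With siLSD1-2 the rho was 0.09.

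**Figure D3:**
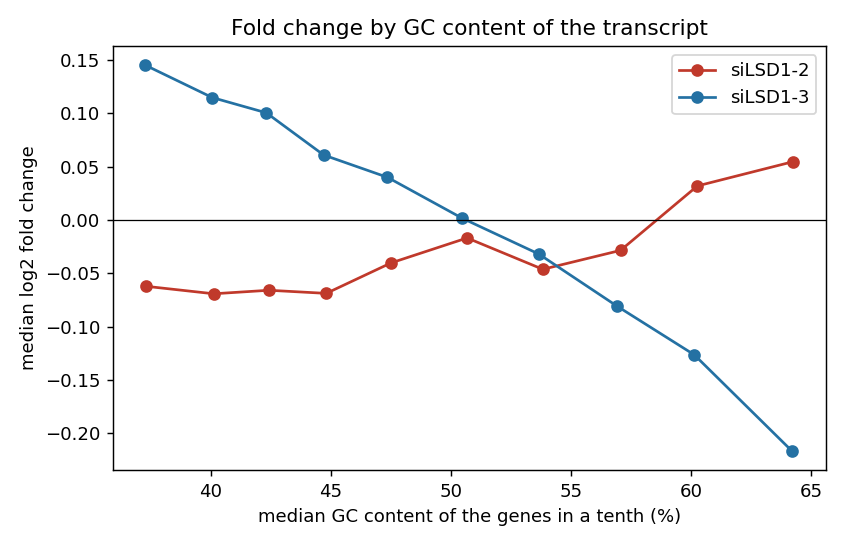
Median log2 fold change of genes in 10 equal groups by GC content, with the median GC content (%) of each group on the horizontal axis. The siLSD1-3 line falls from 0.14 to -0.22, and the siLSD1-2 line goes from -0.06 to 0.05.

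Notch, WNT and Hedgehog responsive genes fell with siLSD1-3 in 17 of 39 cases and rose in 1 (18 and 3 adjusted over the list alone), with a median log2 fold change of -0.38. The camera adjusted p was 5.21e-06 and the adjusted p was 0.508 with an estimated correlation. After the GC trend of each library was removed the median was -0.37 (camera adjusted p = 5.98e-05). The Notch target gene HES1 (NM_005524, chromosome 3, 193853931 to 193856401) fell from 14.4 ± 0.0863 to 7.91 ± 0.337 CPM (-0.85, SE 0.10, adjusted p = 0.00283), HEYL from 168 ± 3.51 to 94.2 ± 19.6 CPM (-0.86) and HEY1 from 118 ± 5.95 to 79.9 ± 7.24 CPM (-0.56). The Hedgehog receptor gene PTCH1, which overlaps LOC100507346, fell from 102 ± 16.4 to 56.4 ± 4.84 CPM (-0.85). A fall was not particular to siLSD1-3 for each of these genes. In the main fit HEYL and HEY1 fell more with siLSD1-2 (siLSD1-2 minus siLSD1-3 -0.53 and -0.40). These calls were lost in 12 alternatives for HEYL and 14 for HEY1. For HES1 and PTCH1 the difference was 0.84 and 0.55. With siLSD1-2, 12 of 38 members of the list fell and 10 rose. Inflammatory cytokine genes rose in 7 of 20 cases and fell in 0 (8 and 2 adjusted over the list alone; median 0.33), with a camera adjusted p of 0.0486 and an adjusted p of 0.618 with an estimated correlation. The cytokine list did not pass without control library b (adjusted p = 0.0556). It has 29 fixed members, and those too low in controls pass the filter only where they rise, so 7 of 20 overstates the share that rose. CCL2 rose from 0.211 ± 0.157 to 1.36 ± 0.313 CPM (2.32).

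The other 28 lists did not pass with siLSD1-3. Integrins rose in 6 of 20 cases and fell in 2 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0652, and 0.00719 with the letter block; unblocked adjusted p = 0.508 with an estimated correlation). ITGA3 rose from 58.5 ± 6.85 to 102 ± 3.14 CPM (0.80, SE 0.09, adjusted p = 0.00283), ITGA5 from 110 ± 5.58 to 171 ± 15.6 CPM (0.63) and ITGA10 from 4.06 ± 0.47 to 11 ± 2.59 CPM (1.40). Matrix proteases and inhibitors rose in 12 of 41 cases and fell in 5 (15 and 6 adjusted over the list alone; camera adjusted p = 0.118, and 0.0228 with the block; unblocked adjusted p = 0.508 with an estimated correlation), and PLAUR rose from 49 ± 5.5 to 95.2 ± 7.52 CPM (0.96). Muscle differentiation genes fell in 6 of 47 cases and rose in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.0675, and 1.71e-05 with the block; unblocked adjusted p = 0.873 with an estimated correlation). Of 50 proliferation genes 7 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.22). Of 47 interferon-stimulated genes 6 rose and 3 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.587). SAMD9L (0.99) and IFI44L (1.05) rose. IFIT2 fell from 108 ± 17.6 to 47.7 ± 16.5 CPM (-1.21, SE 0.22, adjusted p = 0.0119), and its adjusted p was 0.0535 without siLSD1-3 library c. The remaining 23 lists had camera adjusted p-values from 0.133 to 0.99.

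Both siRNAs raised 640 genes in common and lowered 417. C3AR1 changed by 3.50 and 3.11 on the log2 scale with siLSD1-2 and siLSD1-3, SIGLEC15 by 3.13 and 2.54, GNA15 by 3.37 and 2.74, the cytokine subunit gene EBI3 by 4.01 and 2.36, and the myosin gene MYH15 by 3.33 and 2.43. The synaptic gene SYT1 changed by 0.91 and 1.11. RGR changed by -1.89 and -1.77, CHST8 by -1.58 and -2.07, ZDHHC22 by -1.51 and -1.31, and HEY1 by -0.95 and -0.56. Among 14773 genes tested in both experiments, independent lists of these sizes would share 247.9 higher and 225.3 lower genes. Opposite directions were passed by 123 genes (higher with siLSD1-2, 239.8 by independence) and 69 genes (lower with siLSD1-2, 232.9 by independence). With the letter block the shared total, 1057, became 2826. Of these, 1543 were higher (848.3 by independence) and 1283 lower (872.0 by independence). The opposite directions held 566 genes (852.4 by independence) and 483 genes (867.7 by independence), 1049 in sum against 192. Without control library a, b or c of experiment 2 the shared total became 381, 694 or 275, and without siLSD1-3 library a or c it became 648 or 381. Fold changes of the 2 siRNAs correlated across genes at r = 0.41 (Spearman rho 0.29). Genes are not independent replicates, so no p-value is given.

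**Figure D4:**
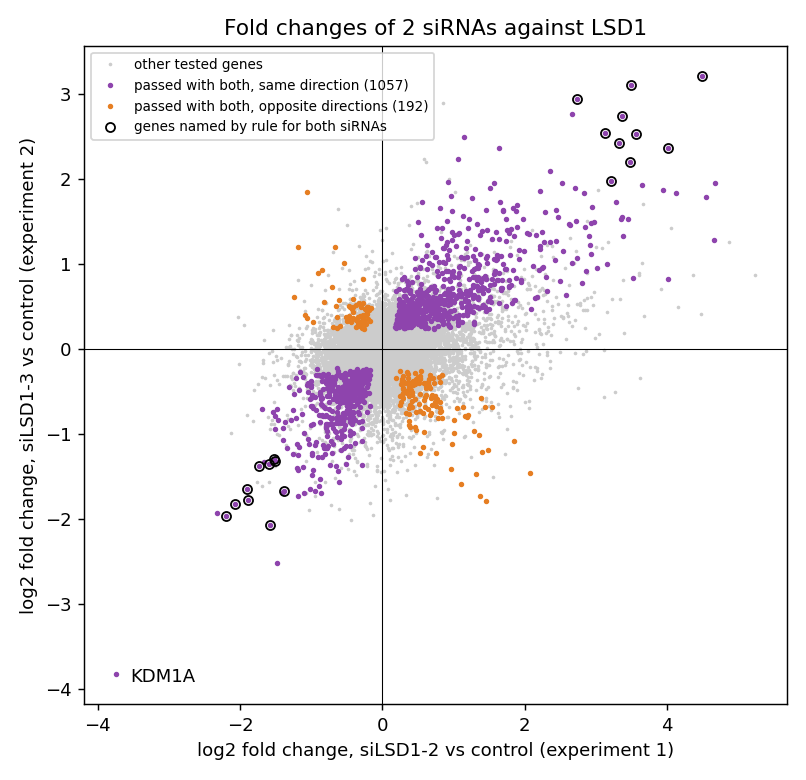
Log2 fold change with siLSD1-2 (horizontal) against that with siLSD1-3 (vertical) for 14773 genes. Purple points passed with both siRNAs in the same direction (1057), orange points in opposite directions (192), and circles mark genes named by the rule for both.

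The difference between the siRNAs' fold changes was tested in 1 fit of all 12 libraries. The log2 fold change of siLSD1-2 minus that of siLSD1-3 was 4.34 for CLDN4 (adjusted p = 0.000101), 2.60 for IFIT2, 1.67 for ITGA3 and 1.31 for the adhesion molecule gene MCAM, which rose with siLSD1-2 (0.57) and fell with siLSD1-3 (-0.75). It was -1.54 for MSTN, -0.88 for AURKB and -2.43 for COL1A2. The mean level of COL1A2 was 72.6 CPM in the controls of experiment 1 and 13.4 CPM in those of experiment 2. The aldo-keto reductase gene AKR1C3 (NM_003739, chromosome 10, 5136568 to 5149878) fell with siLSD1-2 (-1.06) and rose with siLSD1-3 (1.85), a difference of -2.92 (adjusted p = 0.000287). HES1 was at 0.01 with siLSD1-2 and its difference was 0.84 (adjusted p = 0.00364). In all, 15482 genes were tested, of which 2106 were higher and 2009 lower with siLSD1-2 than with siLSD1-3, relative to own controls (4115 in sum, 6986 with the letter block, 2672 without siLSD1-2 library a). Each of the 192 genes that passed in opposite directions without the block also passed this test, as did 222 of the 1057 that passed in the same direction. The experiment and the siRNA cannot be told apart in this comparison.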

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

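The tests of spread and of the experiments, the 3 tests of interferon-stimulated genes, and the thinning test with the letter block were chosen only after the result was seen. The results here were picked out because the effects of siLSD1-2 and siLSD1-3, each against its own controls, differed by a test of the difference itself (limma, adjusted p below 0.05, or camera for lists). All values are log2 fold changes of siLSD1-2 minus those of siLSD1-3.

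The difference passed for 4115 genes. Of the 100 pairs of splits that regroup the 6 libraries of each experiment, 1, the real pair, gave as many genes. The highest other pair gave 3548, with the real groups of experiment 1 kept and those of experiment 2 mixed, and the highest other pair that parts each letter pair gave 2121. Only 4 splits per experiment part each letter pair, too few for a share under 0.05 among their pairs. Each mixed split keeps more knockdown than control libraries on its knockdown side, so it dilutes the effect of an siRNA without removing it. This count therefore does not test the difference alone.

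Of the 16 lists past camera's threshold at the preset correlation (0 with an estimated correlation, where the lowest adjusted p was 0.115, with 7 at an unadjusted p below 0.05, and 22 with fry), 14 had a positive median. The medians were 0.44 for integrins, 0.27 for focal adhesion and integrin adaptors, 0.33 for immunoglobulin-superfamily adhesion molecules, 0.32 for basement membrane, 0.60 for matricellular and matrix glycoproteins, 0.68 for matrix proteases and inhibitors, and 0.47 for ephrins, semaphorins and plexins. They were 0.71 for epithelial markers, 0.68 for interferon-stimulated genes, 0.50 for neuronal genes repressed by REST, 0.43 for YAP and TGF-beta responsive genes, 0.26 for Notch, WNT and Hedgehog responsive genes, 0.60 for inflammatory cytokines and 1.32 for endothelial markers. The 2 negative medians were -0.65 for proliferation and -0.29 for ribosomal proteins.

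Among genes of adhesion and matrix, the difference was 1.67 for ITGA3, 1.26 for ITGB3, 1.79 for ITGA11, 0.55 for ITGA5, 3.76 for ITGAX, 0.78 for CAV2, 1.39 for NTM, 0.88 for ICAM1, 1.22 for L1CAM, 1.12 for THY1, 1.31 for MCAM, 2.84 for TNXB, 0.48 for LUM and -2.43 for COL1A2. For proteases, their inhibitors and guidance molecules it was 1.26 for PLAUR, 0.76 for PLAU, 2.05 for MMP1, 1.56 for EFNA2, 0.80 for SEMA7A, 0.90 for SEMA3C and 2.71 for ROBO4. Among markers of other cell types it was 4.34 for CLDN4, 2.11 for MUC1, 2.29 for CD68, 1.79 for LAPTM5, 1.54 for TIE1, 1.32 for FLT1, 3.59 for PTPRN and 0.73 for SYT11. For the interferon, YAP and p53 lists it was 2.60 for IFIT2, 1.68 for IFIT3, 1.28 for ANKRD1, 1.29 for CTGF and 0.60 for PHLDA3. For the cytokine subunit gene EBI3, which is in none of the fixed lists, it was 1.62. In the Notch, WNT and Hedgehog list it was 0.84 for HES1, 0.55 for PTCH1, 0.31 for FZD7, -0.40 for HEY1 and -0.53 for HEYL.

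For muscle genes and regulators the difference was 0.89 for FBXO32, -0.98 for NEB, -1.05 for MYOD1 and -1.54 for MSTN. For proliferation, RNA interference and ribosomal protein genes it was -0.71 for CDT1, -0.88 for AURKB, -0.88 for CDC45, -0.59 for AGO2, -0.53 for DROSHA, -0.44 for RPS16 and -0.81 for RPL22. Other named genes had 4.04 (RRAD), 3.94 (GALNT15), 3.80 (LPAR5), 3.47 (ABCC3), 3.36 (GPR17), 2.73 (TRPV2), 1.80 (PADI2) and 1.22 (SLC16A6), and in the other direction -1.84 (ARHGAP15), -2.25 (SLC7A3), -2.30 (TAS2R19), -2.32 (STXBP5L), -2.41 (TDRD1) and -2.92 (AKR1C3). Adjusted p-values of these 65 genes ran from 0.000101 to 0.0488. For 13 of them (CAV2, CDT1, FLT1, FZD7, HEY1, HEYL, ITGA11, ITGA5, LAPTM5, LUM, PADI2, RPS16 and SEMA7A) the call was lost in at least 1 alternative, with adjusted p-values from 0.0502 to 0.129.

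Interferon-stimulated genes rose with siLSD1-2 (median 0.87) and their difference between siRNAs passed upward for 33 of 47 members and downward for 2. The highest median among 10000 random lists matched on mean expression was 0.26, which argues against a rise of all genes at that level. The abundant blood cell transcripts PTPRC, CD74, HLA-DRA, HBA1 and HBB summed to at most 0.283 CPM in a siLSD1-2 library. The summed group mean of the interferon-stimulated genes rose by 1695 CPM. These transcripts were picked from the fixed blood cell list after their levels were seen, so they cannot decide whether blood cells added RNA. Other members of that list rose (CD68, LAPTM5 and LYZ) or were lower (ITGB2 and CORO1A) and decide nothing. The list median of the difference was 0.68 (camera adjusted p = 1.94e-12, adjusted p = 0.156 with an estimated correlation), with KDM1A lowered to 8.58 and 7.08% of control. The list was flagged by this same difference, which did not pass with an estimated correlation. The difference is therefore no separate test of the loss of KDM1A mRNA as the whole cause. In siLSD1-2 libraries a, b and c KDM1A was at 5.71, 4.70 and 15.3% of the control mean. Undecided by these values are RNA from blood cells and the loss of KDM1A mRNA as the whole cause. Open and untested are a response to the siRNA duplex itself, other targets of either siRNA, KDM1A protein levels and a difference between the experiments. A candidate explanation is a response specific to siLSD1-2 or to experiment 1. These cannot be told apart because 0 siRNA groups had libraries in both experiments.

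More genes changed with siLSD1-2 (7001) than with siLSD1-3 (2065). With each library thinned to 31.2 M reads the ratio of the counts was 3.48 (median of 5 draws) and 1.54 with the letter block, which argues against a difference in depth. The SD of the log2 fold changes after their error variance was subtracted was 0.58 with siLSD1-2 and 0.35 with siLSD1-3, a ratio of 1.67 (1.61 with the block), which argues against a larger spread between siLSD1-3 replicates as the whole cause. Because the block took the counts to 9046 and 5779, spread between letter pairs may still account for part of the gap. A difference between the siRNAs and one between the experiments cannot be told apart, since 0 siRNA groups had libraries in both.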

How the results depend on the processing

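The letter block, the GC trend removal, the fit without a pair of libraries, the pseudocounts of 0.5 and 1 and edgeR on recovered reads were chosen only after the data were seen. KDM1A was lower in each setting run, from -4.26 to -3.41 with siLSD1-2 and from -3.96 to -3.75 with siLSD1-3 as single libraries were left out. The difference of KDM1A between siRNAs (0.07, not called) ran from -0.46 to 0.40, with the sign turned at -0.46 without siLSD1-2 library c (adjusted p = 0.048); the cause was not tested beyond that library's higher KDM1A level.

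With single libraries left out, which leaves fewer samples, genes changed by siLSD1-2 ranged from 4936 to 7385, those changed by siLSD1-3 from 444 to 3566, those changed the same way by both from 275 to 1561 and those that differ from 2672 to 4907. Lists changed by siLSD1-2 ranged from 17 to 19 and by siLSD1-3 from 3 to 6, and the correlation of fold changes from 0.38 to 0.44. Testing each deposited row, which repeats genes, gave 12690, 3987, 1994 and 7606 rows in the order siLSD1-2, siLSD1-3, both and difference. DESeq2 gave 7505, 2899, 1452 and 4667, and edgeR on recovered reads 7244 and 2038 for the single siRNAs. The replicate block by letter gave 5779 for siLSD1-3, 2826 for both and 6986 for the difference, and the block with the GC trend removed 6197, 3238 and 7155. The fit without the c pair of experiment 1 and the b pair of experiment 2 gave 3784 for siLSD1-3 and 1781 for both. The cause was not tested for these. The correlation was 0.48 with the GC trend removed and 0.37 for the 10258 genes of at least 10 CPM; the cause was not tested.

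Lists changed by siLSD1-3 numbered 4 without a filter, 5 with the replicate block, 4 with the GC trend removed, 8 with both and 7 with fry, and the cause was not tested beyond fry's not comparing a list with other genes. With an estimated correlation, 0 lists passed for siLSD1-2 (18 at the preset correlation) and 0 for siLSD1-3 (2). At an unadjusted p below 0.05 these were 3 and 2, and fry called 23 and 7; the cause was not tested. The block by letter replaced the planned replicate number, which the columns do not carry, and besides the calls given beside it in the report changed no other list call. For each siRNA, the genes called without the block (7001 and 2065) were among those called with it, with the same sign.

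Among 60 list results (20 called) and 780 alternatives, 31 lost a call, 20 of them with the estimated correlation and 8 with a library left out, 35 gained one and 0 reversed. The p53 call was also lost without a filter (adjusted p = 0.0656) and with the GC trend removed (0.065), with a range of 0.0181 to 0.0791 over the settings at the preset correlation and 0.365 with the estimated one, and the cytokine call of siLSD1-3 without the b pair (0.0664). Among 212 gene results (170 called) and 2951 alternatives, 133 lost a call, 123 with a library left out, and 59 gained one. Among 111 gene differences (65 called) and 2214 alternatives, 100 lost a call, 84 with a library left out, 41 gained one and 1 reversed. Other scalings changed the share of higher calls by under 10 percentage points (siLSD1-2 52.4%, 51.9% and 55.2%; siLSD1-3 51.3%, 50.3% and 49.0% with TMM, DESeq2's factors and totals only). For the difference, 2106 higher and 2009 lower genes became 2405 and 1606 with totals only and 2256 and 1731 with the CPM filter, so that balance depends on these choices.

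In the simulated sets, whose changed genes lay above a minimum mean read count, 61.8% of genes changed by 1.5 fold were recovered for siLSD1-3. Splits of the 6 libraries of an experiment number 10, the real one included, too few for a share under 0.05. Each mixed split keeps more knockdown than control libraries on its knockdown side, so part of the knockdown effect remains in it. For genes, 1 split (the real one, with 7001 genes) was as large for siLSD1-2 and the highest other gave 0, and 1 (the real one, with 2065) for siLSD1-3 and the highest other gave 1. For lists, 3 splits gave at least the real 18 for siLSD1-2 (highest other 20, or 13 among splits that part each letter pair), the other 2 of them with control library a or b in place of siLSD1-2 library c. For siLSD1-3, 8 gave at least the real 2 (highest other 9, or 2 among splits that part each letter pair). The 6 siLSD1-3 splits that keep a letter pair on 1 side gave from 1 to 9 lists and the other 3 besides the real one from 1 to 2. In each of these splits 0 or 1 genes passed. For siLSD1-2, splits that keep a letter pair gave from 10 to 20 lists and the other 3 from 9 to 13. The ranges overlap for either siRNA, so they do not settle whether the pairing of the samples sets the number of lists. For genes changed the same way by both siRNAs, 1 of 100 pairs of splits, the real one with 1057, was as large and the highest other gave 0. Only 4 splits per experiment part each letter pair, too few for a share under 0.05 among their pairs, and since mixed splits called at most 1 gene the count for both follows from those of the single siRNAs.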

Other observations

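The tests of gene families, of the GC trend with siLSD1-2 and of lists after GC trend removal were chosen only after the result was seen. Genes that share a symbol stem, with at least 15 measured members, were tested as 86 families with camera. With siLSD1-2, 18 families passed at the preset correlation and fry called 43, while the lowest adjusted p with an estimated correlation was 0.686. The 6 described were chosen after their values were seen, and the other 12 were GPR and SLC (positive medians) and RPL, RPS, RBM, EIF, CEP, PHF, DDX, NDUFA, ZNF and TAF (negative medians). After GC trend removal DDX (adjusted p = 0.0519), TAF (0.0531) and ZNF (0.0645) did not pass. With siLSD1-2, the clustered protocadherin alpha genes, which encode adhesion molecules of neurons, rose in 15 of 15 cases (median log2 fold change 0.61, camera adjusted p = 7.04e-07, adjusted p = 0.686 with an estimated correlation). Their transcripts share 3' exons, so the reads of 1 member count for the others and the 15 values are not separate. Genes of RAB GTPases, which direct vesicle traffic, rose in 29 of 67 cases and fell in 3 (median 0.20, camera adjusted p = 0.000285, adjusted p = 0.686 with an estimated correlation).

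Nucleoporin genes fell with siLSD1-2 in 16 of 20 cases and rose in 0 (median -0.33, camera adjusted p = 0.000285, adjusted p = 0.686 with an estimated correlation). Genes of the large mitochondrial ribosome subunit fell in 21 of 51 cases and rose in 1 (median -0.26, camera adjusted p = 0.000285, adjusted p = 0.73 with an estimated correlation), and those of the small subunit fell in 13 of 30 and rose in 0 (median -0.19, camera adjusted p = 0.00772, adjusted p = 0.739 with an estimated correlation). RAD genes, most of them of DNA repair, fell in 14 of 21 cases and rose in 1 (median -0.39, camera adjusted p = 0.00798, adjusted p = 0.686 with an estimated correlation). With siLSD1-3, 0 families passed at the preset correlation (lowest camera adjusted p = 0.154) and 10 had an unadjusted p below 0.05, while fry called 2.

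Fold changes with siLSD1-3 followed GC content (rho -0.44 across genes). Removing the GC trend per library left the Notch, WNT and Hedgehog list at a median of -0.37 (camera adjusted p = 5.98e-05), which argues against the trend as the cause of that list's call at the preset correlation. With an estimated correlation and no GC removal the list had an adjusted p = 0.508. The rho with siLSD1-2 was 0.0933, with KDM1A mRNA lowered by a similar factor. GC slopes differed between libraries of the same group, from -0.081 to 0.003 in the controls of experiment 1, and siRNA and experiment are confounded. The comparison therefore does not decide whether the loss of KDM1A mRNA alone set the trend. The similarity in KDM1A level depends on siLSD1-2 library c. Without it the KDM1A log2 fold change was -4.26 with siLSD1-2, against -3.83 with siLSD1-3. The highest GC slope of a siLSD1-3 library was 0.0488 log2 per 10 percentage points of GC, above the lowest control slope of 0.043, so a chance difference between single libraries may account for the trend. The siLSD1-3 slope was lower than that of the same-letter control by 0.243, 0.0587 and 0.0988 in pairs a, b and c, and what else could set these slopes apart was not tested.

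The authors' own table, at their adjusted p below 0.05, gives 6631 transcripts higher and 6087 lower with siLSD1-2 and 2207 higher and 2357 lower with siLSD1-3, of 38763 transcripts each. Its log2 fold changes for KDM1A were -3.57 and -3.84. Across tested genes, its fold changes correlated with the refit at 0.991 for either siRNA.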
